A study of Homo sapiens with 2 samples.

How the data were processed

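Total RNA of MCF7 cells treated with b-AP15 or with DMSO was labelled with biotin and hybridised to Affymetrix GeneChip arrays, per the labels' protocols. Each treatment has 1 array. The deposited values are linear intensity values, 1 per probe set, made with MAS5, per the submitters' processing notes. MAS5 summarises the perfect-match and mismatch probes of a probe set into 1 signal and scales each array by a single factor. The version and settings are not given in the sources used here. With 2% of the probe sets trimmed at each end, both arrays had a mean signal of 500.1, so the authors had scaled both to a common trimmed mean. Values reached 65747 on the b-AP15 array and 56320 on the DMSO array and were all above 0. Detection calls were not used here. No genome was used, so no coordinates are given.

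Probe sets were named from the platform annotation, which gives 1 gene for 41097 probe sets, the ACTB and GAPDH array controls included, and several genes for 1801. A further 11721 probe sets other than controls are unnamed here. Entrez identifiers matched the RefSeq gene table for 41043 of the probe sets with 1 gene, and 0 symbols changed. Probe sets with several genes or none were not used in gene results. Each gene was represented by its probe set with the highest mean log2 signal over both arrays. The SD over all measured probe sets of a gene is given as a measure of technical disagreement. It is not a replicate error.

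The log2 ratio of b-AP15 over DMSO was computed from the deposited intensity values with no further scaling. A floor was set at the median, over all 54613 probe sets that are not controls, of the brighter of the 2 signals, which was 86.3. Signals below it were set to it, and genes with both signals below it were left out, which kept 12543 of 19775 genes. Where 1 signal was at the floor (1645 genes) the ratio is a lower bound. Low signals differed between the arrays: the median log2 ratio was 0.43 over the 27306 probe sets below the floor on both arrays and -0.01 over those above it on both.

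With 1 array per condition no test could be made. Genes were counted when they differed at least 2-fold, and "higher" and "lower" refer to these 2 arrays. For 27 gene lists fixed before the data were examined, the median log2 ratio of the measured members was placed among the medians of 10000 random lists of the same size, matched on mean signal in 10 bins. Lists at or below percentile 2.5 or at or above 97.5 were described as outside, and lists with fewer than 5 measured genes were given as values only. A percentile describes these 2 arrays and is not a p-value, because genes of a list are not independent. Some genes are in 2 lists, such as SLC7A11 and ATF3. The named genes were fixed by rule: the 12 largest ratios in each direction among genes above the floor on both arrays whose measured probe sets had 1 sign, the 5 largest lower bounds in each direction under the same condition on sign, up to 4 members of each list with the largest absolute ratios, and 12 stress and proteasome genes whatever their values. Other list members named to describe a list were chosen after their values were seen.

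The procedure was tested on simulated data made from the DMSO array over 12387 genes, with noise of SD 0.473 in log2 ratio, the robust spread of the real ratios. The changed genes were drawn only from genes with DMSO signals well above the floor, so their rates do not cover dim genes. The noise was the same at every signal. In the real data the interquartile range of the log2 ratio was 0.70 at mean log2 signals of 6 to 8 and 0.39 at 12 to 17. Genes raised 4-fold (28 genes) or lowered 4-fold (29 genes) were called in 100% of cases. Genes raised 2-fold were called in 46.4% of 28, genes lowered 2-fold in 24.1% of 29 and unchanged genes in 3.18% of 12162. With so few changed genes, the rates for raised and lowered genes are imprecise and their difference is not interpreted. Of 200 unshifted lists of randomly drawn genes with independent noise, 4.5% lay outside the central range. This rate does not carry over to lists of genes that vary together. Alternatives fixed before the data were examined were median centring, quantile normalisation and a loess fit on mean signal, floors at percentiles 25 and 75, no floor with 16 units added, the median over a gene's probe sets, and leaving out probe sets whose suffix marks possible matches to several transcripts. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.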

Results

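Gene expression was measured in MCF7 cells, an established human breast cancer line that carries the estrogen receptor and has luminal epithelial features. One culture received b-AP15 at 1 µM for 6 hours, and a control culture received the vehicle, 0.1% DMSO, for 6 hours. b-AP15 is a small molecule described by the submitters as a proteasome inhibitor, and it is known to act on USP14 and UCHL5, the deubiquitinases bound to the regulatory particle of the proteasome. The comparison asks which transcripts differ after a short exposure to the compound. Each condition was represented by 1 array with 54613 probe sets other than controls, so no difference below has a replicate check and no p-value is given. All differences describe these 2 arrays. The number of arrays limits the precision. The median signal was 78.2 on the b-AP15 array and 59.1 on the DMSO array. A probe set was counted as measured where the brighter of its 2 signals reached a floor of 86.3, which 47.9% of probe sets did on the b-AP15 array and 43.4% on the DMSO array. The log2 signals of the 22541 probe sets above the floor on both arrays correlated with a Pearson r of 0.961 across probe sets, which are not independent replicates.

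The 18 hybridisation spike probe sets had a median log2 ratio of -0.000621 ± 0.126 (SD over probe sets). The dimmest, those of bioB, ranged from -0.24 to 0.02. The brightest, those of cre, were all positive, from 0.12 to 0.23. Ratios of that size among the brightest genes cannot be told apart from such a difference between the arrays. The 3' over 5' signal ratio, a measure of RNA integrity, was 0.976 with b-AP15 and 0.970 with DMSO for GAPDH, and 1.224 and 1.222 for ACTB.

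Stress response genes had the largest differences between the arrays. The ratios given are those of each gene's brightest probe set unless stated otherwise. HSPA6, a stress-inducible cytosolic HSP70 chaperone, had a signal of 32950 with b-AP15 and 92.8 with DMSO, a 355-fold higher value, and its 2 probe sets gave log2 ratios of 8.13 and 8.47. HMOX1, which encodes the haem-degrading enzyme heme oxygenase 1, was 74.1-fold higher (signals 31236 and 421, 1 probe set). CSRP2, a LIM-domain protein, was 30.3-fold higher, and DNAJA4, a co-chaperone of HSP70, was 29.7-fold higher, with log2 ratios from 1.24 to 5.49 over its 4 probe sets. The other genes among the 12 with the largest positive ratios were DNAJB4 (15.9-fold), DDIT3 (13.8-fold), ATF3 (13.7-fold), HSPA4L (13.4-fold), CHAC1 (13.1-fold), ZFAND2A (12.9-fold), MAP1B (10.6-fold) and SLC7A11 (10.4-fold). Probe sets of several of these genes disagreed in size: the log2 ratios ranged from 0.08 to 3.41 for MAP1B, from 2.43 to 3.99 for DNAJB4, from 3.56 to 4.92 for CSRP2, from 2.74 to 3.78 for ATF3 and from 2.11 to 3.38 for SLC7A11. Among genes at the floor on the DMSO array, the ratio is a lower bound: RGCC was at least 12.8-fold higher from its brightest probe set but had a log2 ratio of 0.11 from its second, RGS2 at least 12.6-fold, the chemokine CCL26 at least 11.3-fold, HSPA1L at least 9.14-fold (log2 ratio 1.66 from its second probe set) and LINC00304 at least 8.15-fold.

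Lower values were smaller in size and included several cell division genes. E2F8, a repressor of the E2F family, was 4.89-fold lower with b-AP15 (signals 285 and 1394). The homeobox gene IRX3 was 4.60-fold lower (3999 and 18404), and the sialyltransferase gene ST8SIA4 was 4.56-fold lower, with log2 ratios from -2.19 to -1.22 over its 4 probe sets. P2RY2, FBXO5, PLEKHG3, CYP1A1, TICRR, SLC9A3-AS1, CENPI, KIF20A and GLCE completed the 12 largest and were between 3.16-fold and 3.64-fold lower. The second probe set of PLEKHG3 had a log2 ratio of -0.71. Over the alternative settings, PLEKHG3 and 5 others fell short of 2-fold at their smallest. The others were CENPI (-0.19), TICRR (-0.47), GLCE (-0.52), SLC9A3-AS1 (-0.59) and P2RY2 (-0.73). These 5 values came with the floor at percentile 75, which was 437.5 and lay above their b-AP15 signals of 155 to 204. They are lower bounds in size, not weaker ratios. KIF20A stayed at least 2-fold lower under all alternatives, and FBXO5 and CYP1A1 under the 7 of 8 that gave them a value. CYP1A1 was unmeasured with the floor at percentile 75, as its DMSO signal was 418. FBXO5 encodes an inhibitor of the anaphase-promoting complex, TICRR a factor in the start of DNA replication, CENPI a centromere protein and KIF20A a kinesin of cytokinesis. Among genes at the floor with b-AP15, ADAM33 was at least 4.26-fold lower, AFAP1L2 at least 3.94-fold, TLN2 at least 3.48-fold, ZBTB14 at least 3.36-fold and PCSK7 at least 3.18-fold. The second probe sets of ZBTB14 and PCSK7 had log2 ratios of only -0.39 and -0.22.

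In total, 616 of the 12543 measured genes (4.91%) were at least 2-fold higher with b-AP15 and 279 (2.22%) were at least 2-fold lower. In the simulation, 3.18% of unchanged genes were called over both directions, so part of these counts may be noise. The DMSO signal was at the floor for 161 of the higher genes, and the b-AP15 signal was at the floor for 31 of the lower genes. Of the genes at least 8-fold apart, 21 were higher and 0 lower. The split between higher and lower depends on the scaling. Of the genes 2-fold apart, 68.8% were higher with the deposited values, 62.1% after quantile normalisation and 62.5% after loess. Only 20.1% were higher after each array was centred on its median. That step moved the median log2 ratio of all measured genes from 0.01 to -0.39. The array medians that it makes equal, 78.2 and 59.1, lie below the floor of 86.3. Median centring lowered the log2 ratio of genes above the floor on both arrays by 0.40, so positive ratios smaller than that change sign under it. Separate probe sets of one gene differed by a pooled SD of 0.379 in log2 ratio over the 6044 genes with more than 1 measured probe set. All measured probe sets had the same sign for 238 of the 261 higher genes that had more than 1, and for 105 of the 143 such lower genes. All were at least 2-fold apart in that direction for 105 of these 261 higher genes and 24 of these 143 lower genes.

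**Figure D1:**
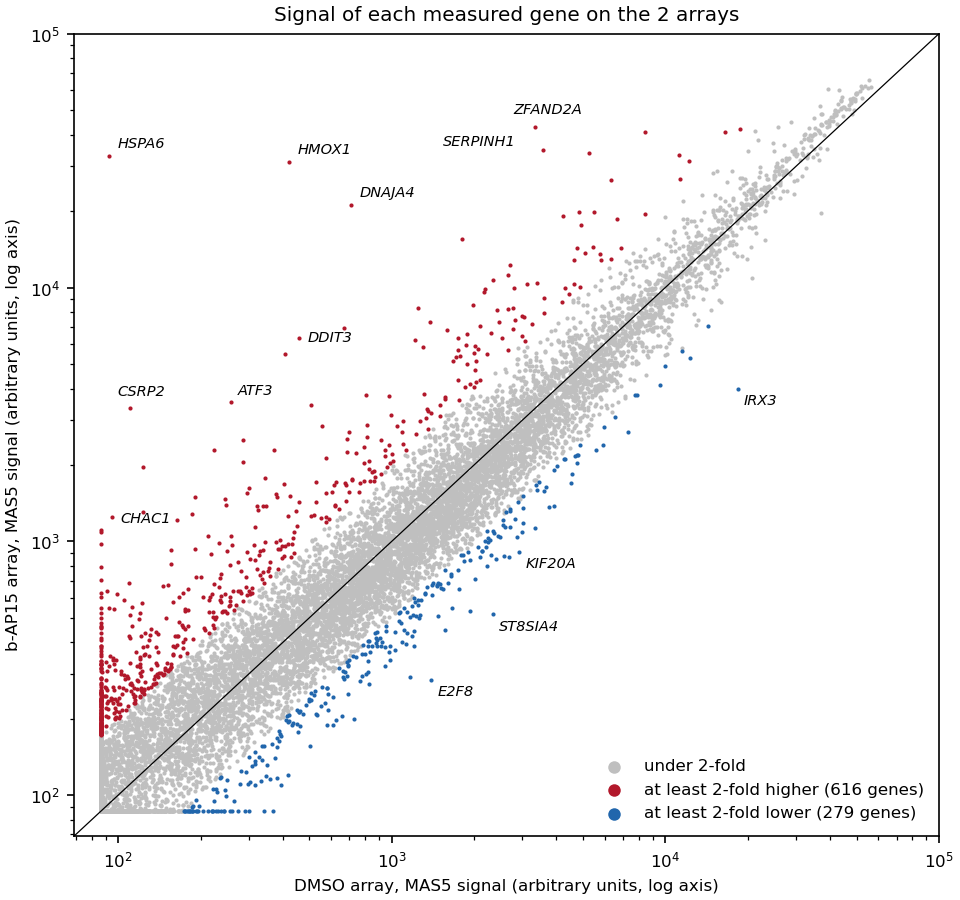
MAS5 signal of each of the 12543 measured genes on the DMSO array (x axis) and the b-AP15 array (y axis), in arbitrary units on log axes, with signals under the floor of 86.3 drawn at the floor and the line of equal signal in black. Red points are the 616 genes at least 2-fold higher and blue points the 279 at least 2-fold lower with b-AP15; HSPA6, HMOX1 and CSRP2 lie farthest above the line.

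**Figure D2:**
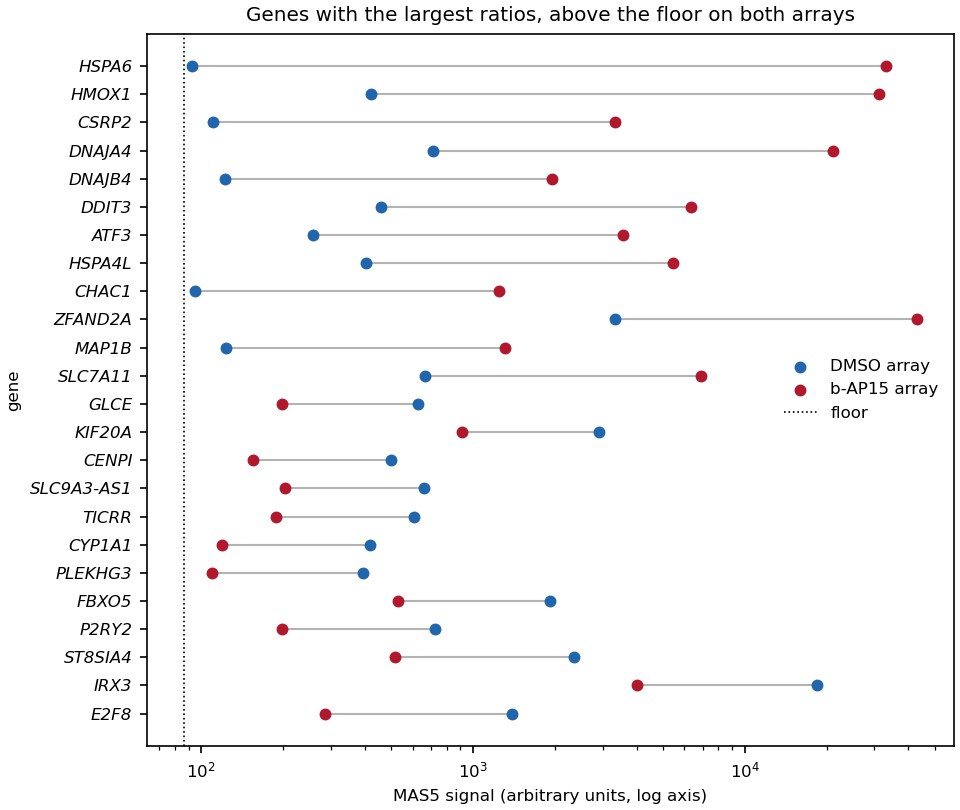
MAS5 signals (arbitrary units, log axis) of the 12 genes with the largest positive and the 12 with the largest negative log2 ratio among genes above the floor on both arrays whose probe sets had 1 sign, 1 array per condition. The gap is widest for HSPA6 (92.8 with DMSO, 32950 with b-AP15), and among the lower genes for E2F8 (1394 with DMSO, 285 with b-AP15).

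The heat shock response was the most displaced of the gene lists. All 24 measured members were higher with b-AP15 (HSP90AA1 became slightly negative after median centring), 19 of them at least 2-fold, and the list's median log2 ratio was 1.49. That median lay above the medians of all 10000 random lists of the same size and signal, 95% of which fell between -0.17 and 0.16. Besides HSPA6, DNAJA4, DNAJB4 and HSPA4L, the list included DNAJB1, an HSP40 co-chaperone, at a log2 ratio of 2.69 (probe set SD 0.23, 2 probe sets), the collagen chaperone gene SERPINH1 at 3.28, HSPH1 at 2.28 (up to 3.24 over 3 probe sets) and BAG3, a co-chaperone of selective autophagy, at 1.57. The smallest ratios from brightest probe sets were those of the chaperone genes HSP90AA1 (0.36) and HSPD1 (0.63), with DMSO signals of 44143 and 39286. Their other probe sets gave larger ratios for HSPD1, up to 2.65 (probe set SD 1.02, 4 probe sets), and the 4 of HSP90AA1 ranged from 0.30 to 0.92. HSPA1A and HSPA1B, near-identical neighbours, had no probe set assigned to either gene alone and are not reported.

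**Figure D3:**
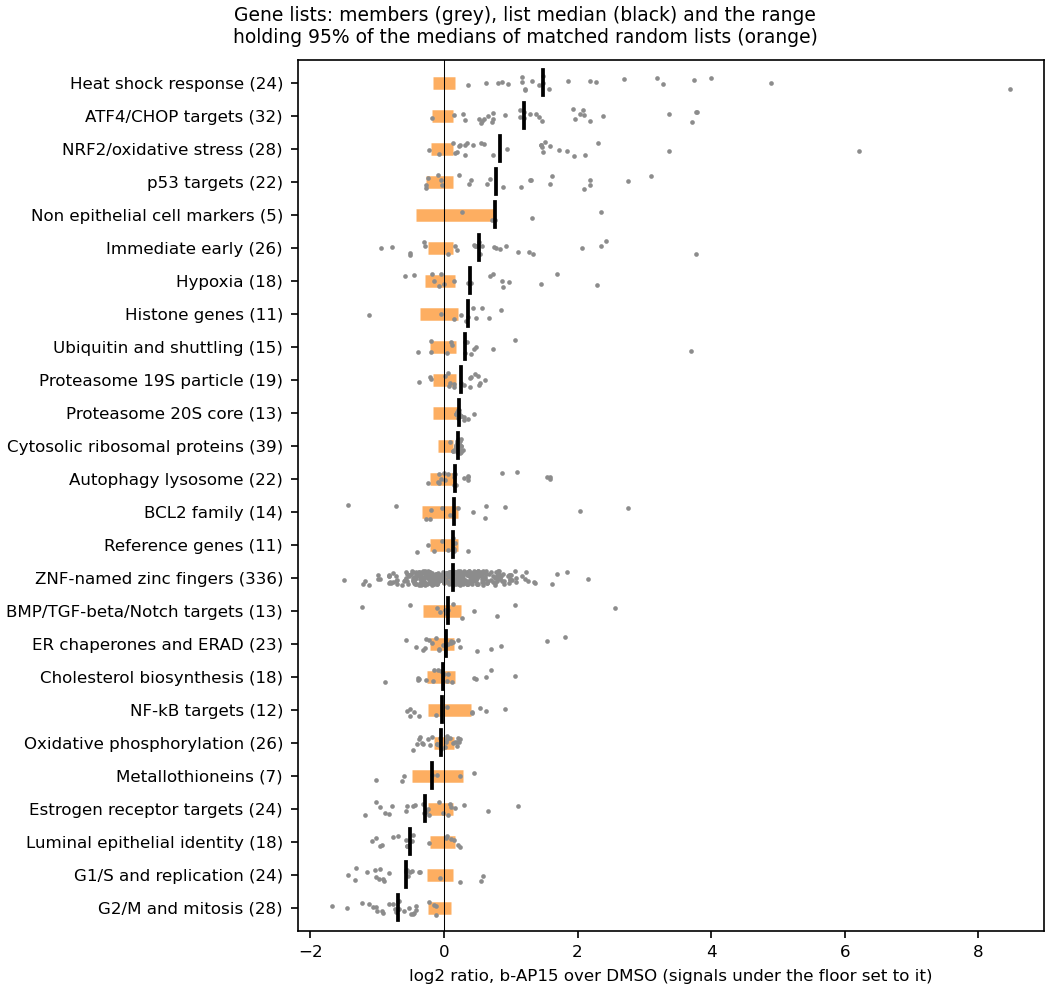
Log2 ratio of b-AP15 over DMSO for the measured members of 26 gene lists (grey points, number measured in brackets), with the list median (black bar) and the range that holds 95% of the medians of 10000 random lists matched on signal (orange). The heat shock, ATF4/CHOP, NRF2 and p53 lists have medians between 0.78 and 1.49, and the G2/M and G1/S lists have medians of -0.69 and -0.57.

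Targets of ATF4 and CHOP, the transcription factors of the integrated stress response, were higher with b-AP15 in 31 of 32 measured members, 19 of them at least 2-fold. The list's median log2 ratio was 1.20, above all 10000 random lists. DDIT3, which encodes CHOP itself, had a log2 ratio of 3.79, ATF3 3.78 (probe set SD 0.73, 2 probe sets), the glutathione-degrading enzyme gene CHAC1 3.71 and the cystine transporter gene SLC7A11 3.38. The asparagine synthetase gene ASNS (2.19), TRIB3 (2.08), the PSAT1 gene of serine synthesis (1.94) and the eIF2alpha phosphatase subunit gene PPP1R15A (2.38) were also higher. Genes of aminoacyl-tRNA synthetases had smaller ratios, with CARS1 at 1.14, GARS1 at 0.74 and NARS1 at 0.29.

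Chaperones and degradation factors of the endoplasmic reticulum did not move as a group. Of 23 measured members, 12 were higher and 11 lower, only DNAJB9 (log2 ratio 1.81, probe set SD 0.50, 3 probe sets) and HERPUD1 (1.54) were at least 2-fold apart by the brightest probe set, and the median of 0.03 (-0.37 after median centring) lay at percentile 76.2 of the random lists. HSPA5, the gene of the chaperone BiP, had a log2 ratio of 0.71 from its brightest probe set and 1.75 from its second. XBP1, a transcription factor of the unfolded protein response, was lower at -0.57, PDIA4 had -0.32 and HYOU1 0.03.

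Genes of the oxidative stress response that depend on NRF2 were higher in 26 of 28 measured members, and 13 were at least 2-fold higher. The median log2 ratio was 0.84, above all 10000 random lists. After HMOX1 (6.21) and SLC7A11 (3.38) the largest ratios were those of OSGIN1 (2.31) and the sulfiredoxin gene SRXN1 (2.11). TXNRD1 (1.85), GCLM (1.73) and the aldo-keto reductase genes AKR1C1 (1.51) and AKR1C2 (1.48), a pair similar enough in sequence to share probes, were also higher. NQO1, a widely used NRF2 marker, had 0.32 from a DMSO signal of 16210. The 7 measured metallothionein-list genes had a median of -0.17 at percentile 37.5, with MT1H lowest at -1.02 and MT1E highest at 0.44. In the autophagy and lysosome list the median was 0.16 (percentile 96.2, inside the central 95% of random lists but above it under 5 of the 8 alternative settings), and after median centring it was -0.24. Of its 22 measured genes 4 were at least 2-fold higher: the cargo receptor gene SQSTM1 (1.59), MAP1LC3B (1.09, and 2.33 from its second probe set), and, as lower bounds, GABARAPL1 (1.59) and TFEB (1.55).

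Proteasome subunit genes showed mostly small positive ratios from their brightest probe sets, and none of these reached 2-fold. Other probe sets did for PSMA5 (log2 ratio 2.37), PSMD11 (2.26), PSMA3 (1.29), PSMD6 (1.17) and PSMB7 (1.02), while PSMB2 had one at -0.20. By the brightest probe set, all 13 measured genes of the 20S core were higher, with a median log2 ratio of 0.23 (percentile 98.7), and 16 of 19 genes of the 19S regulatory particle were higher, with a median of 0.26 (percentile 99.9). PSMA3 had the largest ratio of the core (0.45), and PSMD1 (0.62), PSMD12 (0.53), ADRM1 (0.53) and PSMC1 (0.51) those of the regulatory particle. These signs rest on the scaling: after median centring the medians were -0.17 and -0.14, still above the all-gene median of -0.39. The 20S list fell inside the central 95% of random lists after quantile normalisation (percentile 96.9) and without probe sets that may match several transcripts (95.8). Among the 3 proteasome deubiquitinases, PSMD14 had a log2 ratio of 0.47, USP14 0.42 (probe set SD 0.03, 3 probe sets) and UCHL5 0.09 (probe set SD 0.14, 3 probe sets), the last with probe sets of both signs. Ubiquitin and shuttling factor genes had a median of 0.32 (percentile 99.9, and -0.08 after median centring). In that list of 15 measured genes ZFAND2A, an arsenite-inducible proteasome-associated zinc finger gene, had 3.69 and ZFAND5 had 1.07. The ubiquitin gene UBB had 0.48 from a DMSO signal of 43046.

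The list of p53 targets lay higher with b-AP15, with 16 of 22 measured genes above 0. Its median log2 ratio was 0.78, above all 10000 random lists, and 10 genes were at least 2-fold higher. GADD45A had a log2 ratio of 3.10, PMAIP1, which encodes the pro-apoptotic protein NOXA, 2.76 (probe set SD 0.31, 2 probe sets), GDF15 2.18 (0.59 from its second probe set) and the cyclin-dependent kinase inhibitor gene CDKN1A 2.18. The death receptor gene TNFRSF10B had 2.10 (4 probe sets from 0.62 to 2.22), FAS 1.62 and MDM2 1.15 (8 probe sets from 0.11 to 1.90). The pro-apoptotic gene BAX had -0.03, RRM2B -0.05 and TP53I3 -0.27. Within the BCL2 family the median was 0.15 (percentile 93.8, and -0.13 after median centring), with PMAIP1 and HRK higher and BCL2 lower at -1.44. The brightest probe set of HRK gave 2.03 with DMSO at the floor, and its 4 probe sets ranged from 0.72 to 2.03 with a median of 1.11. The 3 probe sets of BCL2 disagreed, ranging from -1.44 to 0.99.

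Immediate early genes had a median log2 ratio of 0.53, above all 10000 random lists, with 7 of 26 measured genes at least 2-fold higher and 0 lower. After ATF3 the largest were FOSL1 (a lower bound of 2.43), the phosphatase gene DUSP1 (2.35, with probe sets from -0.33 to 2.35) and IER5 (2.07). JUN had 0.78, EGR1 0.20 and MYC 0.16, while JUNB had -0.78 and DUSP4 -0.94. The 12 measured NF-kB targets had a median of -0.04 (percentile 21.5). TNFAIP3 had 0.92 and NFKB1 -0.55, while IL6 and TNFAIP2 had only lower bounds, 0.54 and 0.42, as their DMSO signals were below the floor. The 3 probe sets of ICAM1 ranged from -0.50 to 1.11.

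Cell cycle genes were lower with b-AP15. All 28 measured genes of G2/M and mitosis had negative log2 ratios, with a median of -0.69, below all 10000 random lists, and 7 were at least 2-fold lower. KIF20A had -1.68, the Aurora kinase gene AURKB -1.46 (probe set SD 0.08, 2 probe sets), CDK1 -1.22 (probe set SD 0.13, 4 probe sets) and KIF23 -1.12 (-0.45 from its second probe set). In the G1/S and replication list 21 of 24 measured genes were lower, 6 of them at least 2-fold, and the median of -0.57 was again below all 10000 random lists. FEN1 had -1.43, CDC25A -1.33 (3 probe sets from -1.33 to -0.22, median -0.39), MCM2 -1.31 and CCNE2 -1.15, whereas SLBP (0.58), CDC6 (0.56) and CCNE1 (0.24) were higher.

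Genes of luminal identity and estrogen signalling were lower in part. In the luminal list 12 of 18 measured genes were lower and the median log2 ratio was -0.51, below all 10000 random lists. ERBB3 had -1.08, SPDEF -1.02, the estrogen receptor gene ESR1 -0.96 and GATA3 -0.92 (3 probe sets from -1.62 to -0.92), but probe sets of ERBB3 and SPDEF had both signs, and the 4 of ESR1 ranged from -0.96 to -0.03 with a median of -0.15. The keratin genes KRT8 (0.11), KRT18 (0.21) and KRT19 (0.05) were near 0. Their DMSO signals, 42489 to 49718, lay near the top of the range, where a difference could be compressed. Estrogen receptor targets had a median of -0.28 at percentile 0.92, with MYB at -1.19, PGR at -1.01 (-0.05 from its second probe set) and CCND1 at -0.88 against FHL2 at 1.11 and TFF1 at 0.31. This list moved inside the central 95% of the random lists under 4 of the 8 alternative settings. Of 20 markers of non-epithelial cells 5 were measured, all 5 higher, with a median of 0.76 at percentile 97.6 that fell inside the central 95% under 3 alternatives, to 83.6 with no floor. COL1A1 had 2.36 (probe set SD 0.93, 4 probe sets, signals 2854 and 558) and CD14, as a lower bound, 1.32. ACTA2 had 0.76, the endothelial gene PECAM1 0.72 (signals 192 and 116) and COL3A1, also as a lower bound, 0.26. The leukocyte gene PTPRC and the endothelial gene VWF were not measured.

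Other fixed lists gave small shifts. Hypoxia-responsive genes had a median log2 ratio of 0.39 (percentile 99.97, and -0.02 after median centring), led by ADM (2.29), VEGFA (1.70, 4 probe sets from 0.65 to 1.70) and NDRG1 (1.46), while EGLN3 had -0.58; without probe sets that may match several transcripts the list lay at percentile 79.8. Histone genes had 0.36 (percentile 99.7, and -0.04 after median centring), with H4C8 at 0.85 and the linker histone gene H1-10 at -1.12. All 39 measured cytosolic ribosomal protein genes were slightly higher, with a median of 0.21 (percentile 99.97), which became -0.19 after median centring and -0.00186 after quantile normalisation, where the percentile was 90.3. Zinc finger genes named ZNF, 336 of them measured, had a median of 0.13 (percentile 99.6, and -0.26 after median centring), with ZNF222 highest at 2.15, and lay at percentile 83.6 without probe sets that may match several transcripts. The lists of oxidative phosphorylation (median -0.05, percentile 26.2), cholesterol synthesis (-0.02, percentile 63.9), BMP, TGF-beta and Notch targets (0.06, percentile 73.4, and -0.34 after median centring) and reference genes (0.13, percentile 84.5, and -0.27, -0.08 and -0.01 after median centring, quantile normalisation and loess) lay inside the central 95% of random lists. The Notch effector genes HEY1 and HES1 had opposite signs, at 2.56 and -1.22, and both probe sets of each agreed. Of the 26 lists with enough measured genes, 13 lay above and 4 below that range. About 1.3 would fall outside it if the genes of a list varied independently. They do not, so that number is no measure of chance here.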

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

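The tests in this part were chosen after the results were seen. Groups of 1 array allow no check for outlying samples.

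Ribosomal RNA controls, which the comparisons above do not use, differed between the arrays. The 28S control probe set for the 5' part was 2.81 times as bright with b-AP15 (signals 21777 and 7738), and that for the middle part 2.08 times. The 3' 28S probe set was below the floor on both arrays (65.7 and 75.9). Degraded RNA on 1 array was not seen in the 3' over 5' ratios of GAPDH and ACTB, which differed between the arrays by at most 1.01 times. The signals behind these ratios ran from 35754 to 48051, near the top of the range. A difference could be compressed there, so this test cannot exclude degradation. The STAT1 control, with 3' and 5' signals of 2040 and 104 with b-AP15 and 2466 and 84.6 with DMSO, was not part of this test, and its 5' signals lay at or near the floor. More ribosomal RNA of every kind is argued against by the 18S controls, where the 5' and middle probe sets were lower with b-AP15, the lowest at a log2 ratio of -0.264 against an SD of 0.126 over the spike controls, although the 3' 18S probe set was 1.79 times as bright. That 18S value also goes against a difference of 28S RNA alone. What set these controls apart stays open, and no biological explanation was tested.

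Probe sets without a single gene name also held signal: 215 of the 4292 measured ones (5.01%) were at least 2-fold higher with b-AP15 and 65 (1.51%) at least 2-fold lower.

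More genes were at least 2-fold higher than lower, a ratio of 2.21. A higher signal of dim probe sets on the b-AP15 array may account for part of this, because the ratio fell to 1.66 after the trend with signal was removed by loess. More genes were still higher than lower after that step, so the trend that loess removed was not the whole of the excess on these 2 arrays. The interval of that value, 1.45 to 1.91 (from a 95% Wilson interval), treats genes as independent. Genes are not independent, so no conclusion is drawn from the interval. An array-wide brightness factor of the 0.40 in log2 that median centring removes is argued against by the spike controls, whose median log2 ratio was -0.000621. A change in total mRNA per cell stays open, since the spikes were not tied here to cell number, and so does the treatment itself.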

How the results depend on the processing

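No paired analysis was possible because each condition has 1 array. The number of genes at least 2-fold apart depends on the floor and the scaling. It was 1806 higher and 522 lower with the floor at percentile 25, 218 and 138 with the floor at percentile 75, 2205 and 743 with no floor and 16 units added, and 307 and 1224 with median centring. Genes added by a lower floor are dim ones. All 307 genes higher after median centring were among the 616, which was fixed in advance because that step lowers the ratios. Quantile normalisation gave 535 higher and 327 lower, and loess 536 and 322. The heat shock, ATF4/CHOP, NRF2, p53, immediate early, G1/S, G2/M, luminal, 19S proteasome, ubiquitin and histone lists stayed outside the central range, on the same side, under all 8 alternatives. The estrogen receptor list moved inside it with quantile normalisation (percentile 3.05), loess (2.60), the floor at percentile 75 (4.09) and the median over probe sets (4.05). Ribosomal proteins moved inside with quantile normalisation (90.3) and loess (95.8), and the 20S core with quantile normalisation (96.9) and without probe sets that may match several transcripts (95.8), called shared here. Without those probe sets hypoxia (79.8) and ZNF genes (83.6) also moved inside. Non-epithelial markers moved inside with median centring (95.9), the floor at percentile 25 (97.2) and no floor (83.6). The autophagy list moved above the range with quantile normalisation (98.7), loess (98.3), the floor at percentile 75 (97.8), the median over probe sets (99.98) and without shared probe sets (99.1), and the BCL2 family with median centring (98.7). NF-kB targets and non-epithelial markers had too few measured genes for a percentile with the floor at percentile 75, as had metallothioneins and non-epithelial markers without shared probe sets. The cause of these moves was not tested. Of 80 named genes at least 2-fold apart, 55 stayed so under every alternative that gave a value, and 0 changed sign. The count of 55 is no ranking of stability. With the floor at percentile 75 some ratios became lower bounds under 2-fold, while dimmer genes gave no value there. The count of 0 was partly fixed by the selection. Median centring shifts ratios by less than 2-fold, and many of these genes were chosen for probe sets of 1 sign. The ratio of HSPA6 depends on a dim DMSO signal. It ranged in log2 from 6.23, a lower bound with the floor at percentile 75, to 8.55.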

Other observations

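The scan of gene families and all tests in this part were made after the results were seen, except the test of the dimmer endoplasmic reticulum genes, whose prediction was written first. Genes were grouped by the letters of their symbol, which gave 193 families with at least 8 measured genes. Of these, 21 families lay outside the central 95% of random lists. The number would be 9.65 if the genes of a family varied independently, which was not shown. The AKR, DNAJB and HSPA families, which overlap the stress lists, lay above all random lists with medians of 1.11 for AKR and 1.14 for DNAJB. Entries with the stem MRPL, the large-subunit proteins of the mitochondrial ribosome and the antisense RNA MRPL20-AS1, were lower in 40 of 49 measured cases, with a median log2 ratio of -0.22 at percentile 0.37. MRPL18 stood apart from them at 1.85 (signals 19759 and 5495, 1 probe set), the next highest, MRPL58, being at 0.26. Splicing factors of the SRSF family had a median of -0.34 (percentile 1.18), and 6 of 9 were lower, SRSF4 most at -0.54, although its second probe set had 0.29, while SRSF7 had 0.52 (4 probe sets from 0.01 to 0.95). Both families kept their side of the range under median centring, quantile normalisation and loess.

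Entries with the stem KLF, Krüppel-like factor genes and the antisense RNA KLF3-AS1, were higher in 12 of 14 measured cases, with a median of 0.40 (percentile 99.8), with KLF4 at 0.75, KLF2 at 0.57 and KLF5 at -0.38; the values of KLF17 and KLF3-AS1 are lower bounds. Entries with the stem USP, mostly deubiquitinases such as USP14 but also USP6NL and the pseudogene USP32P2, had a median of 0.18 (percentile 99.5, and a median of -0.22 after median centring), with 25 of 43 higher and none 2-fold apart by its brightest probe set. Entries with the stem MCM, which include helicase genes and also MCM3AP and MCM3AP-AS1, were lower in 10 of 11.

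ATF4 and CHOP targets were higher (median 1.20) while the chaperone list of the endoplasmic reticulum was not (median 0.03). A ceiling of the array is argued against, because all 8 heat shock genes with DMSO signals in the range of the brighter chaperones, 4017 to 17568, were at least 2-fold higher. Compression of bright signals was predicted to leave the dimmer 11 chaperone genes with a raised median. Their median was -0.0206, so no such rise was seen. The prediction was written on the median alone, and by it this value counts against compression across the list. Their quartiles, -0.20 and 0.55, show the spread among these genes and not the precision of the median. Because of that spread no firm conclusion is drawn. The dimmer genes do not bear on compression of single genes near the top of the range, which stays open. The choice of probe set also stays open, since with the median over probe sets the list moved to percentile 93.4. No biological explanation was tested, and an effect of the treatment stays open.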
